A study of Mus musculus with 18 samples.

How the data were processed

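Poly(A)-selected RNA of AML12 cells was sequenced as dUTP-stranded libraries on DNA nanoballs, per the labels' protocols. The series has 18 libraries in 6 groups of 3, pemafibrate and DMSO in each of 3 exposure windows, and groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

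The authors deposited 1 table per window, each with 35551 Ensembl mouse gene IDs and 6 libraries, and the values are normalized signal, per the file headers and names: estimated counts per gene scaled by the authors within each window. The column names end as salmon output files do. The aligner or counter version, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Not all low values were whole multiples of what 1 read is worth: within a tolerance of 0.05, 60.7% to 74.6% of values up to 8 reads came out whole. Whole reads were therefore not recovered, no count test was run, and read depth before normalization is unknown. Normalized totals ran from 31461977 to 33884634 per library and the top 10 genes held 4.7% to 5.6% of the signal. The tables were normalized separately, so tests of pemafibrate were made within windows or on differences of within-window effects, and DMSO libraries were not tested between windows. Symbols came from a gene name table that matched 35181 of the IDs, and the other 370 kept their ID.

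Values were analysed as log2(value + 1), which understates the change of low genes. Genes with a mean of at least 10 over the libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each window was fitted on its own 6 libraries, and differences between windows on all 18. The tests within windows and of differences between them, the 30 gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined, and later additions are named as such. Adjustment over a list alone was not part of that plan. It corrects within a list and window, not across lists or windows. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. With an estimated correlation camera has only the degrees of freedom left by the libraries of a fit, few within a window and fewer with the block. It could hardly call a list there, so its lack of calls decides nothing either way. Two-sided tests were used, except that the hypergeometric tests of overlap took the upper tail. Splits and swaps were counted where they gave at least as many calls as the real grouping.

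Replicate numbers were checked for pairing. Deviations from the group means correlated at 0.31 to 0.64 across genes between DMSO and pemafibrate libraries of the same number, in all 9 pairs, and at −0.44 to −0.11 between different numbers. The pairing thus comes from the data together with the numbers in the titles, and results with the replicate number as a block (the paired fit) are printed beside the unpaired ones where they change the call. Standard errors beside fold changes are from the paired fit. A fit of 1 effect common to the 3 windows, with the 9 pairs as blocks, was added after the data had been seen. It treats pairs of the same replicate number in different windows as independent, so windows were also averaged within each number.

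The rule for named genes took, per window, the 10 largest rises and falls past the threshold in the unpaired fit (none passed), every measured core PPARα target, up to 4 genes of the smallest p in each other list, all clock genes as a group, the 5 genes of the smallest p in the unpaired fit of each difference, and Ppara. Aldh1a1, Syt7, Gm10241 and the further genes of the fit over all windows fall outside it and were named after their values were seen. Some genes that the rule or a count covers are not reported here by name. Acot1 and Acot2, Aldh1a1 and Aldh1a7, and the Cyp4a genes are close paralogs, and Gm10241, Gm5537, Gm2223, Gm2058, Gm11425 and Rpl14-ps1 are predicted genes or pseudogenes, so the division of reads between such copies is uncertain.

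The fits were tested on simulated tables built from the libraries' means, replicate offsets and residual spread, with 50 changed genes at each of 4 sizes. For T0 to T24, T14 to T20 and T24 to T30 the paired fit called 88%, 86% and 82% of genes changed 1.5-fold (of 13485, 13384 and 13391 genes tested) and 11, 16 and 4 unchanged genes. The unpaired fit called 68%, 60% and 60% of genes changed 2-fold and no unchanged gene. For the differences T14 to T20 against T24 to T30, T0 to T24 against T14 to T20 and T0 to T24 against T24 to T30, the paired fit called 72%, 74% and 82% of genes whose effect differed 1.5-fold. The simulation gives genes of equal mean the same spread, so real genes may be harder to call. All changed genes had a mean of at least 50, so lower genes were not simulated. Many genes were changed at once, which eases the adjusted threshold, so these shares may be too high for data with few changed genes. Alternatives covered the pseudocount, the filter, rescaling of the libraries, the variance trend, thresholds, a shared fit of all libraries and leaving out libraries or pairs.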

Results

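The response of hepatocytes to pemafibrate, a selective modulator of the nuclear receptor PPARα that regulates genes of fatty acid use, was measured by poly(A) RNA sequencing in AML12 cells, a non-transformed mouse hepatocyte line. The cells had been synchronized in their circadian rhythm and received pemafibrate or its solvent DMSO over 1 of 3 windows. The first window ran from T0 to T24 and served the study as its 24 h reference exposure. The other windows were 6 h exposures, from T14 to T20 to mimic the day and from T24 to T30 to mimic the night. Each of the 6 groups held 3 libraries, 18 in all. The deposited values were normalized signal per gene, and their totals ran from 31461977 to 33884634 per library. Read depth before normalization was not given.

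The libraries separated first by replicate number. The first principal component held 24.3% of the variance of 13258 genes and the second held 15.9%. Differences between replicate numbers made up 84.2% of the first component and 95.4% of the second, and differences between treatments made up 0.018% and 0.58%. Apoe, an apolipoprotein made by hepatocytes and named after its values were seen, averaged 867 ± 87.7 (SD, n = 6) in the libraries of replicate 1, 442 ± 65.2 in replicate 2 and 194 ± 23.2 in replicate 3 over both treatments and all windows. Treatment effects were therefore read both without pairing and within pairs of the same replicate number.

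**Figure D1:**
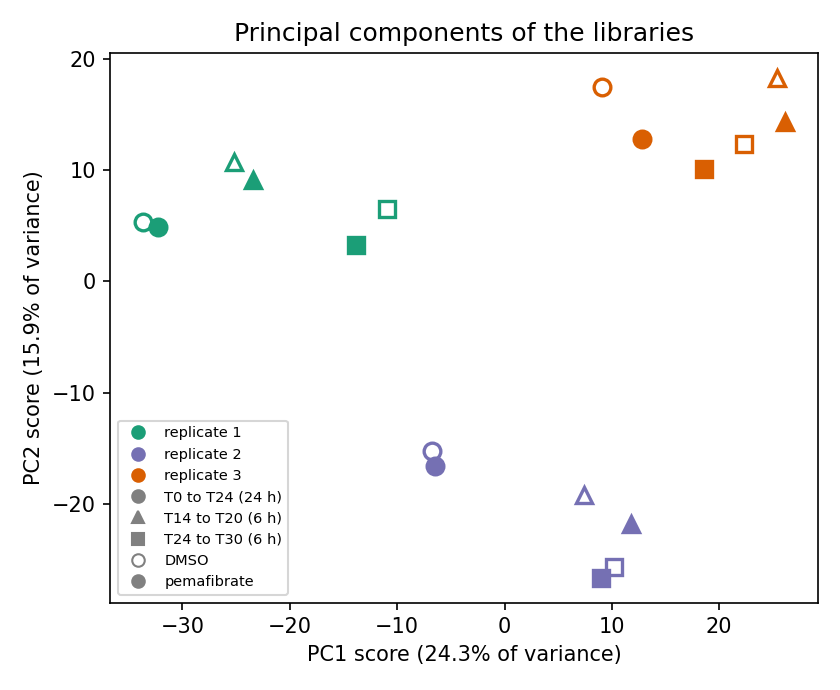
Scores of the 18 libraries on the first 2 principal components of log2(value + 1), with replicate number in colour, window as symbol shape, DMSO open and pemafibrate filled. Libraries of the same replicate number lie together, and the DMSO and pemafibrate libraries of each pair lie close to each other.

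Ppara, which encodes the receptor (ENSMUSG00000022383), was measured in every group. Its signal was 206 ± 24.7 (SD, n = 3) with DMSO and 149 ± 45.7 with pemafibrate over T0 to T24. Over T14 to T20 it was 151 ± 52.0 and 211 ± 71.0, and over T24 to T30 it was 130 ± 45.3 and 168 ± 76.7. None of these differences passed the test in limma, with adjusted p = 0.946, 0.575 and 0.686 in the paired fits.

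After 24 h of exposure (T0 to T24), 7 genes rose and none fell in the paired fit, and all but Aldh1a1 belonged to the core PPARα target list. Among them, Acot1 and Acot2, thioesterases that release fatty acids from coenzyme A in the cytosol and in mitochondria, rose by 0.83 ± 0.05 and 0.95 ± 0.08 on the log2 scale (SE of the paired fit). Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 0.65 ± 0.05, from 1139 ± 157 to 1798 ± 308 (SD, n = 3). Plin2, which coats lipid droplets, and Cpt1a, which controls fatty acid entry into mitochondria, rose by 0.39 ± 0.03 and 0.37 ± 0.03. Aldh1a1, a retinaldehyde dehydrogenase, rose by 0.75 ± 0.03, from 5798 ± 1405 to 9764 ± 2394 (adjusted p = 0.0010).

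Of the 21 genes of the core PPARα list, 16 were above the minimum level and 13 of them had a positive fold change at 24 h. Adjusted over the list alone, 9 rose in the paired fit and 5 in the unpaired fit. Pdk4, the kinase that inhibits pyruvate dehydrogenase, had a log2 fold change of 1.41 ± 0.16, and Creb3l3, a liver transcription factor, 1.43 ± 0.22. Both passed over the list alone (adjusted p = 9.0e-05 and 5.9e-04 in the paired fit) but not over all genes (adjusted p = 0.058 and 0.280). Slc25a20, the carnitine-acylcarnitine carrier, was 0.17 ± 0.06 (adjusted p = 0.039 over the list alone) and did not pass over all genes. Ehhadh, Pex11a, Vnn1, Cd36, Acadm and Acsl1 lay between −0.04 and 0.18 without passing. The list as a whole was higher by camera (adjusted p = 2.4e-18), but not with an estimated correlation (adjusted p = 0.166). The latter form has few degrees of freedom within a window and could hardly call any list. The other 5 members, Fgf21, Cyp4a10, Cyp4a14, Cidec and Fabp1, were below the minimum in every window, with highest values of 2.02 for Fgf21, a secreted metabolic hormone, and 5.02 for Fabp1, a fatty acid binding protein.

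At 24 h mitochondrial fatty acid oxidation had a positive fold change for 22 of 25 genes, with a median of 0.077, and 7 members rose in the paired fit adjusted over the list alone, among them Eci2 (0.27 ± 0.04) and Acadl (0.15 ± 0.05), both enzymes of β-oxidation. Its camera test gave adjusted p = 5.6e-07, and adjusted p = 0.581 with an estimated correlation. Among lipid droplet and lipolysis genes 9 of 13 were positive, and Hilpda, an inhibitor of triglyceride lipolysis, rose by 0.34 ± 0.07 (adjusted p = 0.010 over the list alone). The lipid droplet list, the fatty acid uptake list (6 of 10 positive) and the thermogenic list (4 of 5 positive) were called higher by camera (adjusted p = 5.6e-04, 0.0074 and 7.5e-04), but not with an estimated correlation (adjusted p = 0.166, 0.363 and 0.166). Camera called 5 lists in all at 24 h, and 11 without the pemafibrate library of replicate 3. Ucp2, a mitochondrial carrier, rose by 0.38 ± 0.07 within the thermogenic list (adjusted p = 0.0044 over the list alone). Pdk1, another pyruvate dehydrogenase kinase, rose by 0.38 ± 0.08 within the glucose list (adjusted p = 0.019 over the list alone). Over all genes Eci2, Acadl, Hilpda, Ucp2 and Pdk1 did not pass.

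Without pairing, limma called 0 of 13325 genes at 24 h, with 94 genes at an unadjusted p under 0.05 where chance alone gives 666. So few small values mean that the unpaired p-values ran too large. Differences between replicate numbers enter their error, so the 0 calls do not show that no gene changed. The same holds for the unpaired fits of the other windows and of the differences between windows. With the replicate number as a block it called 7, with 689 genes at an unadjusted p under 0.05. The paired count was 12 without replicate 1 and 4 without replicate 2, and 0 without the variance trend or without the filter on low values. It was 14 in a shared fit of all 18 libraries. Acot1 and Aldh1a1 stayed called whichever pair was left out, and Acot2 and Angptl4 were lost without replicate 2. Plin2 was called only without replicate 2, and Cpt1a in none of these settings.

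**Figure D2:**
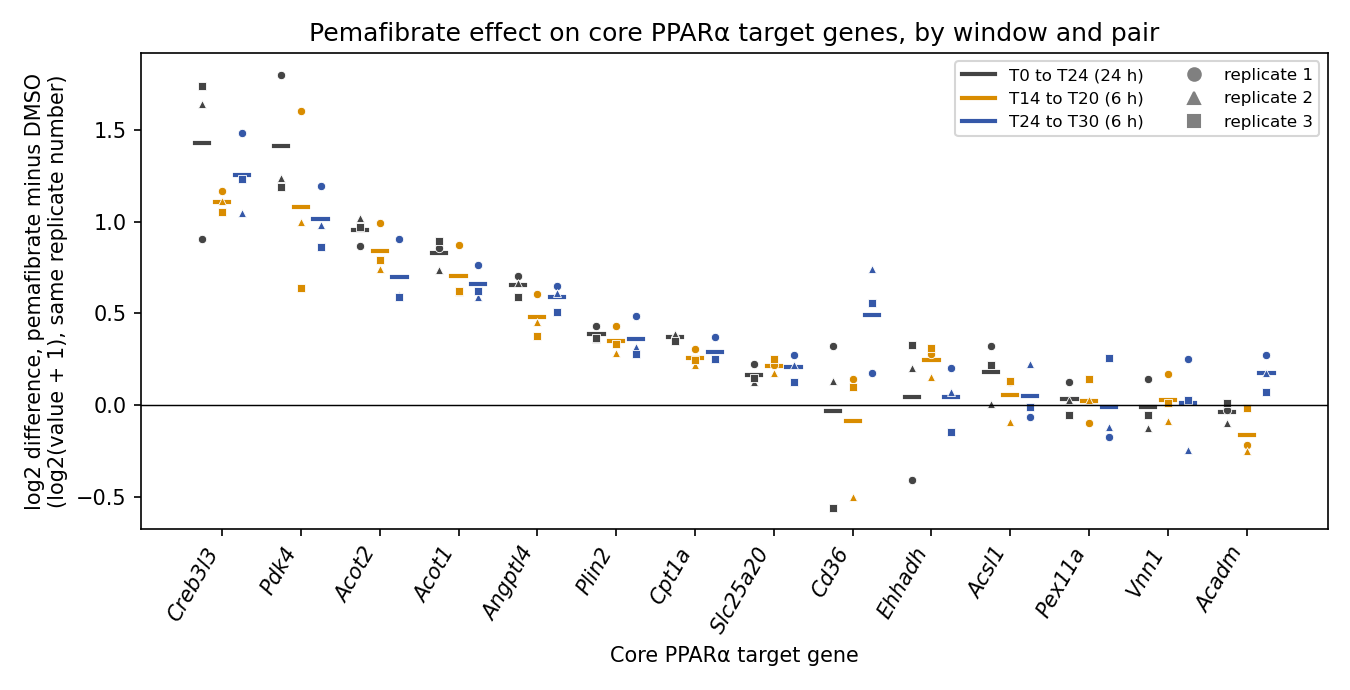
Log2 differences between pemafibrate and DMSO for 14 of the 16 measured core PPARα target genes, with 1 point per pair of the same replicate number and a bar for the mean of the 3 pairs, coloured by window. Creb3l3, Pdk4, Acot2, Acot1, Angptl4, Plin2, Cpt1a and Slc25a20 lay above 0 in all 3 pairs of each window.

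Exposure for 6 h over T14 to T20 raised 4 genes in the paired fit, all of them among those raised at 24 h. Among them, Acot1 rose by 0.71 ± 0.06, from 2199 ± 410 to 3595 ± 706 (SD, n = 3, adjusted p = 0.020), Aldh1a1 by 0.58 ± 0.05 and Plin2 by 0.35 ± 0.03. The predicted gene Gm10241 was lower, at −0.86 ± 0.09 (adjusted p = 0.048). Over T0 to T24 Gm10241 had a fold change of the opposite sign, 0.81 ± 0.24, which did not pass (adjusted p = 0.864). Gm10241 was not called when any of the 3 pairs was left out. Plin2 stayed called only without replicate 2, and Acot1 and Aldh1a1 stayed called whichever pair was left out. Angptl4 (0.48 ± 0.05), Acot2 (0.84 ± 0.09) and Cpt1a (0.26 ± 0.03) were just short of the threshold, with adjusted p = 0.056, 0.051 and 0.065.

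Over the core PPARα list alone, 9 genes rose and Acadm, the medium-chain acyl-CoA dehydrogenase, fell in the paired fit for T14 to T20, and 6 rose in the unpaired fit. Acadm had a log2 fold change of −0.16 ± 0.05 (adjusted p = 0.027 over the list alone, adjusted p = 0.541 over all genes). Pdk4 was 1.08 ± 0.19 and Creb3l3 1.11 ± 0.17, both past the threshold over the list alone. Fold changes were positive for 14 of 16 core genes and for 22 of 25 mitochondrial fatty acid oxidation genes. Crot, the peroxisomal carnitine octanoyltransferase, rose by 0.24 ± 0.03 among peroxisomal genes (adjusted p = 0.0037 over the list alone). Lipe, hormone-sensitive lipase, rose by 0.29 ± 0.07 among lipid droplet genes (adjusted p = 0.020 over the list alone). Neither Crot nor Lipe passed over all genes.

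Camera called 6 lists in this window without pairing and 9 with the replicate number as a block. The core targets, mitochondrial fatty acid oxidation, lipid droplet and fatty acid uptake lists were higher (adjusted p = 6.0e-18, 8.3e-07, 3.8e-05 and 0.042). The mitochondrially encoded transcripts were higher too, for 11 of 13 genes with a median of 0.10 (adjusted p = 4.8e-05), and the ribosomal proteins were lower, for 27 of 30 genes with a median of −0.046 (adjusted p = 0.038). With the block the fatty acid uptake list no longer passed (adjusted p = 0.073). The cholesterol synthesis, peroxisomal, immediate early and cell cycle lists passed only with the block (adjusted p = 0.0035, 0.043, 0.0031 and 0.033), the first 2 higher and the last 2 lower. No list passed with an estimated correlation, where the smallest value was adjusted p = 0.235 unpaired and adjusted p = 0.554 paired. That form has too few degrees of freedom here for its lack of calls to weigh against a list. Fry called 0 lists in this window, with or without the block. With the block it gave adjusted p = 0.168 for the core targets and 0.428 for the mitochondrially encoded transcripts.

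For T14 to T20 limma called 0 of 13210 genes without pairing, with 73 at an unadjusted p under 0.05 where chance gives 660. The replicate block gave 5 calls, 4 higher and 1 lower, and 1075 genes at an unadjusted p under 0.05. TMM rescaling left 2 calls, both higher, upper-quartile rescaling left 4, all higher, and no gene was called without the variance trend or without the filter. Robust settings gave 8 paired calls, the shared fit of all libraries 9 and a 1.5-fold minimum 3. Leaving out the pemafibrate library of replicate 3 let the unpaired fit call the predicted gene Gm5537 (adjusted p = 0.014), and the unpaired list count was 2 without the pemafibrate library of replicate 2.

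Exposure for 6 h over T24 to T30 raised 5 genes in the paired fit. Among them, Acot1 rose by 0.66 ± 0.05, from 2656 ± 533 to 4205 ± 888 (SD, n = 3, adjusted p = 0.013), Angptl4 by 0.59 ± 0.05 and Aldh1a1 by 0.47 ± 0.04. Syt7, a synaptotagmin that acts in calcium-dependent vesicle fusion, rose by 0.89 ± 0.09, from 198 ± 87.6 to 366 ± 154 (adjusted p = 0.047). Syt7 was −0.14 ± 0.21 over T0 to T24 and 0.29 ± 0.19 over T14 to T20, without passing. Syt7 was not called when any of the 3 pairs was left out. Angptl4 stayed called only without replicate 1, and Acot1 and Aldh1a1 only without replicate 1 or replicate 3.

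Over the core PPARα list alone, 10 genes rose in the paired fit and 4 in the unpaired fit for T24 to T30, and 15 of 16 fold changes were positive. Pdk4 was 1.01 ± 0.13, Creb3l3 went from 25.7 ± 9.59 to 64.6 ± 31.6 (SD, n = 3), and Acadm was 0.17 ± 0.05 (adjusted p = 0.016 over the list alone, adjusted p = 0.615 over all genes). Ppard, the PPARδ receptor gene, was 0.30 ± 0.06 and Slc16a6, a monocarboxylate transporter, 0.42 ± 0.13, each past the threshold within its own list (adjusted p = 0.037 and 0.039). Neither Ppard nor Slc16a6 passed over all genes. Camera called the core target, mitochondrial fatty acid oxidation and lipid droplet lists higher (adjusted p = 9.9e-17, 1.8e-05 and 0.0013). The cell cycle list was lower, with a negative fold change for 30 of 30 genes and a median of −0.067 (adjusted p = 0.033 unpaired, adjusted p = 6.8e-08 paired). Its members with the smallest p were Tyms (−0.18 ± 0.04) and Pcna (−0.13 ± 0.04), which act in DNA synthesis, and no member passed by itself. The list also holds Cdkn1a and Cdkn1b, inhibitors of the cell cycle, so genes that drive division and genes that restrain it were both lower. With an estimated correlation none of these lists passed, the smallest value being adjusted p = 0.234 unpaired and adjusted p = 0.418 paired, and the cell cycle list had adjusted p = 0.990 unpaired.

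Without pairing limma called 0 of 13231 genes for T24 to T30, with 123 at an unadjusted p under 0.05 where chance gives 662. The replicate block gave 5 calls and 994 genes at an unadjusted p under 0.05. The paired count was 1 without replicate 2, and that gene was not among the 5. It was 0 without the variance trend or without the filter on low values, and 8 in the shared fit of all libraries.

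Taking the 3 windows together, in a fit added after the windows had been examined, 24 genes rose and 1 fell with the 9 pairs as blocks. Creb3l3 rose by 1.26 ± 0.11 on the log2 scale, Pdk4 by 1.17 ± 0.11, Acot2 by 0.83 ± 0.05 and Acot1 by 0.73 ± 0.04. Aldh1a1 (0.60 ± 0.04), Angptl4 (0.57 ± 0.03), Plin2 (0.37 ± 0.02), Cpt1a (0.31 ± 0.02) and Slc25a20 (0.20 ± 0.03) were also called, and each was higher in 9 of 9 pairs. Further β-oxidation genes were Acaa2 (0.22 ± 0.03), Acadvl (0.16 ± 0.02), Eci2 (0.21 ± 0.03) and the peroxisomal Crot (0.22 ± 0.03). Hsdl2, a peroxisomal dehydrogenase-like protein, rose by 0.51 ± 0.04, and Aldh1a7, a paralog of Aldh1a1, by 0.48 ± 0.06. Hmgcs1, the cytosolic synthase of the cholesterol pathway, rose by 0.12 ± 0.02. Mpst, a sulfurtransferase, fell by 0.17 on the log2 scale (SE 0.03) and was lower in 9 of 9 pairs. Of the 25 genes, 13 belonged to the lists of fatty acid handling and ketogenesis. Averaging the windows within each replicate number, which leaves 3 units, limma called 12 genes, all higher. Crot, Acaa2, Acadvl, Eci2, Slc25a20, Aldh1a7 and Hmgcs1 were then not called (adjusted p = 0.059, 0.151, 0.147, 0.103, 0.178, 0.121 and 0.214), and neither was Mpst (adjusted p = 0.360). The count of 25 was also 12 without replicate 2 and 14 without replicate 1, and 7 with a 1.5-fold minimum.

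The comparison of the day and night windows asks whether the pemafibrate effect depends on circadian time. The night window also came later after synchronization, so clock time and time since synchronization cannot be told apart. The effect over T14 to T20 minus that over T24 to T30 was 0.05 for Acot1 (95% interval −0.13 to 0.22, paired fit), 0.07 for Pdk4 (−0.49 to 0.62), −0.11 for Angptl4 (−0.26 to 0.05) and −0.01 for Plin2 (−0.14 to 0.12). Acadm differed by −0.33 (−0.50 to −0.17), with adjusted p = 0.013 over the core list alone and adjusted p = 0.327 over all genes. The 5 genes with the smallest p in the unpaired fit were Nsun3 (0.59), Zeb1 (0.43), Timm17b (0.45), Apol7b (5.51) and Ppard (−0.59). None of them passed in either fit. Apol7b lay below the minimum level in both windows, so its difference rests on low values. Limma called 0 of 13258 genes in either fit, with 126 genes at an unadjusted p under 0.05 unpaired and 1225 paired where chance gives 663. Without replicate 2 the paired fit called Col7a1 (−1.17, adjusted p = 0.012).

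The 24 h exposure gave somewhat larger estimates than the 6 h exposures for several genes, but no gene passed the test of the difference. Of 16 core targets, the 24 h estimate was the larger for 12 against T14 to T20 and for 10 against T24 to T30. The 24 h window also differs from the others in start and harvest time, so exposure length and clock time cannot be told apart. Against T14 to T20 the effect on Aldh1a1 was larger by 0.17 (95% interval 0.04 to 0.30, paired fit) and on Angptl4 by 0.17 (0.02 to 0.33), both with adjusted p = 0.985 over all genes. Against T24 to T30 the differences were 0.28 (0.15 to 0.41) and 0.07 (−0.09 to 0.22), with adjusted p = 0.537 and 0.847 over all genes. In the unpaired fit the genes with the smallest p against T14 to T20 were Gm2058, Slc6a19 (1.40), Col4a3bp (0.33), Gm11425 and Cep126 (−0.78). Gm2058 lay below the minimum level over T14 to T20. Against T24 to T30 the genes with the smallest p in the unpaired fit were Gm2058, Tnni1 (2.24), Col4a3bp (0.36), Rpl14-ps1 and Lhcgr (−1.77). Tnni1 lay below the minimum level over T24 to T30. The 2 comparisons had 65 and 102 genes at an unadjusted p under 0.05 unpaired and 654 and 1057 paired, and 0 calls in either fit. In the paired fit Rpl14-ps1 was called in both comparisons without replicate 1 (adjusted p = 0.0020 and 5.3e-04), and Gm2223 in both without replicate 3 (adjusted p = 0.030 and 0.022).

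The genes raised in the paired fits overlapped between windows. In all 3 windows 3 genes were called, Acot1 and Aldh1a1 among them, and 9 genes were called in any. The 24 h window shared 4 genes with each 6 h window and the 6 h windows shared 3, where independent lists would share 0.0021, 0.0027 and 0.0015 (exact hypergeometric test across genes, upper tail, p = 2.8e-14, 1.4e-13 and 1.1e-10). The unpaired fits made no calls and so had no overlap. Across all genes tested in both windows, log2 fold changes were nearly unrelated, with Pearson r of 0.022 to 0.048 and Spearman rho of −0.092 to 0.10. These correlations are across genes, which are not independent replicates.

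Clock genes were measured as a group of 23 in each window, and none passed the test of pemafibrate against DMSO, either over all genes or adjusted over the list alone. Among the 21 clock genes with a mean of at least 50, log2 fold changes lay between −0.09 and 0.17 over T0 to T24, between −0.22 and 0.09 over T14 to T20, and between −0.10 and 0.05 over T24 to T30. Usp2, a clock-controlled deubiquitinase of lower signal, was −0.90 ± 0.48, −0.62 ± 0.36 and 0.45 ± 0.35 in these windows. In the DMSO libraries Arntl (Bmal1), the positive arm of the clock, was 353 ± 48.9 (SD, n = 3) at T20, 249 ± 49.6 at T24 and 550 ± 64.0 at T30. Nr1d1, which represses Arntl, was 1951 ± 263, 1785 ± 179 and 677 ± 60.9 at the same times. Dbp, a clock output factor, was 944 ± 203, 1280 ± 251 and 314 ± 92.6. Cry1 was 294 ± 20.9, 404 ± 45.5 and 604 ± 85.5. The tables of the 3 windows were normalized separately, so these levels are set side by side without a test. The T24 libraries had been in DMSO for 24 h and the others for 6 h, so harvest time and length of exposure to DMSO go together. The median shift of all genes between the DMSO tables was 0.011 to 0.041 on the log2 scale.

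**Figure D3:**
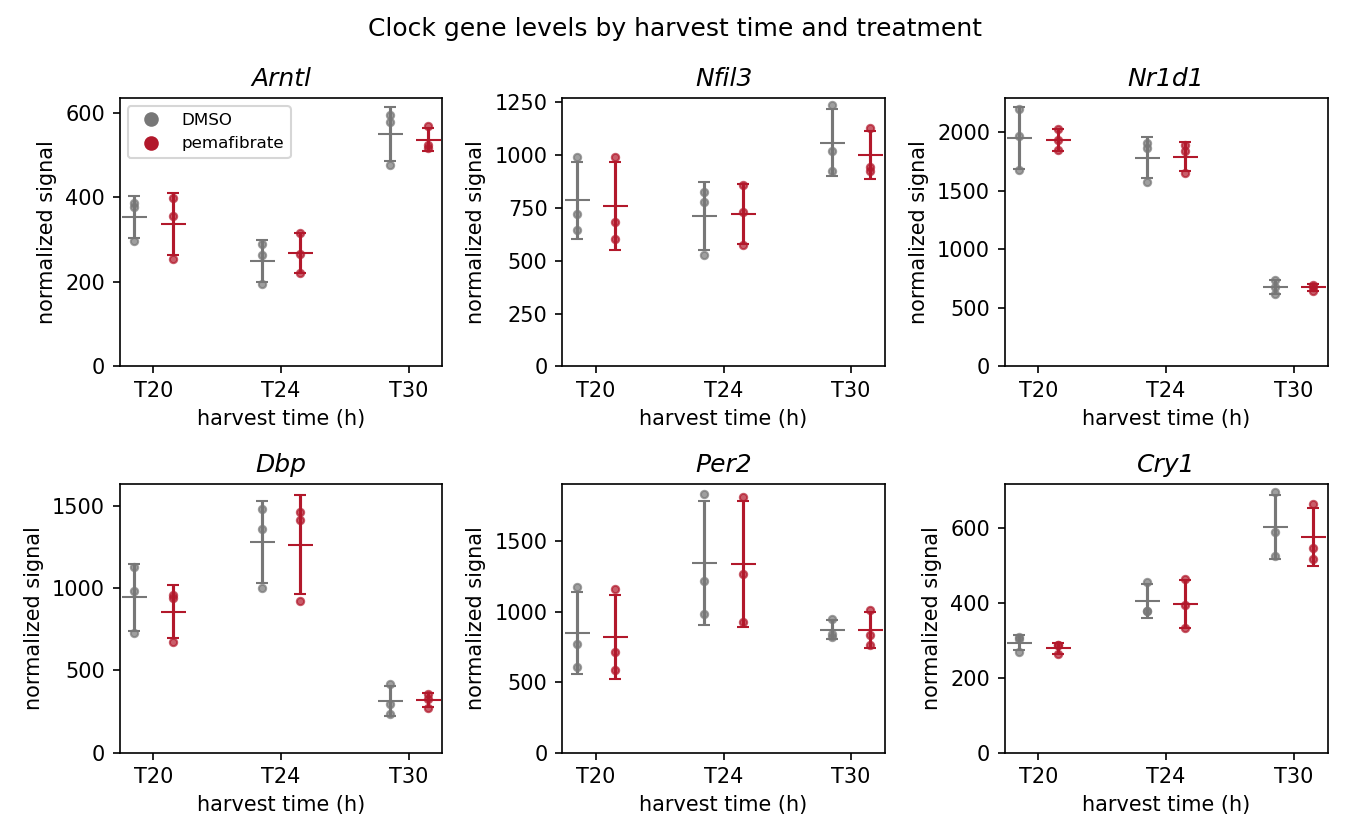
Normalized signal of 6 clock genes by harvest time (T20, T24 and T30) and treatment, with points for the 3 libraries, a horizontal mark for the mean and bars for the SD. Nr1d1 and Dbp with DMSO were at 677 and 314 at T30 against 1785 and 1280 at T24, and pemafibrate means lay within the spread of the DMSO libraries.

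The other 19 of the 30 lists, clock genes included, were called by camera in no window, with or without the block, where the smallest values were adjusted p = 0.065 and 0.062. They covered ketogenesis, microsomal omega oxidation, PPAR receptors and coregulators, fatty acid and triglyceride synthesis, insulin signalling, glucose and glycogen metabolism, bile acid and xenobiotic metabolism, acute phase genes, the unfolded protein response, NRF2 targets, nuclear oxidative phosphorylation genes, extracellular matrix, heat shock genes and markers of hepatocytes, cholangiocytes, stellate cells, macrophages and endothelium. For the 14 of these lists with at least 9 measured genes, median log2 fold changes stayed between −0.055 and 0.059 in every window. Over all 19 lists they ran from −0.28 to 0.35, both for the 4 measured stellate and fibroblast markers, over T24 to T30 and T0 to T24. By fry with the block, acute phase genes were lower over T0 to T24 (adjusted p = 0.0085, median −0.055) and the ketogenesis list was higher over T24 to T30 (adjusted p = 0.040, median 0.13). With the block and an estimated correlation, camera gave adjusted p = 0.517 and 0.628 for them.

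In some lists single genes passed only in the paired fit adjusted over the list alone. PPAR receptors and coregulators had 2 higher over T0 to T24 and 1 higher in each 6 h window. Mitochondrially encoded transcripts had 1 higher over T0 to T24, 2 higher over T14 to T20 and 1 lower over T24 to T30. Fatty acid and triglyceride synthesis had 1 lower over T14 to T20. Over T24 to T30 bile acid and xenobiotic metabolism had 1 lower, and cholangiocyte and progenitor markers had 1 higher.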

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

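All tests of explanations in this part were chosen only after the results were seen. What each would show was written down before the tests of the mitochondrially encoded and cell cycle lists were run, but for the splits only after they had been run. Flagged here are lists or core genes whose pemafibrate effect differed between windows by a test of the difference. None of the list differences passed with an estimated correlation, where the values ranged from adjusted p = 0.304 to 0.994 in limma's camera. By fry with the block, the flagged mitochondrially encoded, cell cycle and core target differences did not pass either (adjusted p from 0.083 to 0.603).

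The mitochondrially encoded transcripts had a larger effect over T14 to T20 than over T24 to T30, by a median of 0.11 on the log2 scale over 13 genes (camera adjusted p = 0.021, and 0.0022 with the block). Their effect over T0 to T24 was smaller than over T14 to T20 by a median of −0.097 (adjusted p = 0.0049, and 0.0022 with the block). Replicates 1 and 2 over T14 to T20 had medians of 0.16 and 0.20, and replicate 3 had −0.039. The median difference between the 6 h windows was 0.056 without replicate 1, between the bounds set in advance, 0.066 without replicate 2 and 0.21 without replicate 3, so whether 1 pair sets the shift cannot be told apart with 3 pairs. Library scaling stays open, since the tables were already normalized and subtracting the median of all genes, −0.0012, left 0.12 by construction. After a trend on transcript length and GC content was removed the median difference was 0.023, so such a trend may account for most of it, and an effect of the exposure window stays open and untested beyond this.

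The cell cycle list had a higher effect over T0 to T24 than over T24 to T30, by a median of 0.093 over 30 genes (camera with the block, adjusted p = 4.5e-07), and than over T14 to T20 by 0.044 (adjusted p = 0.015). Without the block neither passed (adjusted p = 0.922 and 0.791), nor with the block and an estimated correlation (adjusted p = 0.304 and 0.599). Over T24 to T30 the list was lower in 3 of 3 pairs, with 26, 25 and 26 of 30 genes below 0 (exact sign tests across genes, which are not independent, p = 5.9e-05, 3.2e-04 and 5.9e-05), which argues against 1 pair setting the shift. The mean shift was −0.075 before and −0.070 ± 0.008 (SE over genes) after the trend on length and GC content was removed, which argues against that trend. A difference in cell density or cycle stage between the DMSO and pemafibrate cultures stays open and was not tested, and an effect of pemafibrate on proliferation is a hypothesis only. The cell cycle inhibitors Cdkn1a and Cdkn1b were among the genes lower over T24 to T30.

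With the block, the core PPARα targets had a larger effect over T0 to T24 than over T14 to T20 by a median of 0.11 (camera adjusted p = 0.034), and the 4 measured thermogenic genes by 0.23 (adjusted p = 0.034). Neither passed without the block (adjusted p = 0.598 and 0.303) or with the block and an estimated correlation (adjusted p = 0.599 for both). Against T24 to T30 the medians with the block were 0.056 (adjusted p = 0.607) and 0.034 (adjusted p = 0.831). By fry with the block the thermogenic difference between T0 to T24 and T14 to T20 also passed (adjusted p = 0.029). Fry with the block called these genes lower over T14 to T20 than over T24 to T30 too, by a median of −0.12 (adjusted p = 0.036). Camera with the block did not (adjusted p = 0.140), nor did fry without it (adjusted p = 0.967). Acadm had a lower effect over T14 to T20 than over T24 to T30 by −0.33 on the log2 scale (paired fit in limma, adjusted p = 0.013 over the core list alone, adjusted p = 0.327 over all genes), with 0 of 3 pairs higher in the first window and 3 of 3 in the second.

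Other splits were counted for each number of calls. The 6 libraries of a window make 10 splits and the pairs allow 4 swaps, too few for a share under 0.05. The unpaired fits called 0 genes in each window, which 10 of 10 splits matched, and the highest other splits called 3, 1 and 2 genes for T0 to T24, T14 to T20 and T24 to T30. The paired fits called 7, 5 and 5, matched by 1 of 4 swaps, the real one, and the highest others were 3, 0 and 2. The list counts of 5, 6 and 4 were matched by 7, 5 and 7 of 10 splits, and the highest others were 12, 9 and 11. Those came from splits that part only 1 pair and so follow the replicate numbers, and the splits that part all 3 pairs reached 3, 1 and 1. For the 3 differences the real count of 0 was matched by 10 of 10 splits of the pair differences, and the highest other was 1 in each. For the fit over all windows, of 100 drawn swaps within the 9 pairs, 1 gave 25 calls, the real one, a share under 0.05, and the highest other gave 1. The swaps treat the 9 pairs as independent, which libraries of the same replicate number may not be. With windows averaged per replicate number the real count was 12, matched by 1 of 4 swaps, and the highest other was 1.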

How the results depend on the processing

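Fits of 1 effect over all windows, the alternatives of the paired fits and the combinations of block with other list tests were added after seeing the data. The unpaired counts of 0 per window and per difference stayed at 0 under other pseudocounts, filters, rescaling, trend settings, thresholds and the shared fit, and the replicate block alone moved the window counts, to 7, 5 and 5 for T0 to T24, T14 to T20 and T24 to T30. The unpaired p-values ran too large in the main setting, so this stability does not show that no gene changed. Leaving out 1 library gave 0 to 1 calls for T14 to T20 and 0 elsewhere. The paired counts were 0 in each window without the low-value filter (more genes tested) and without the trend, 14, 9 and 8 in a shared fit of all 18 libraries, and 3, 0 and 0 at adjusted p under 0.01. For T14 to T20 they were also 2 with TMM rescaling, 8 with robust settings and 3 with a 1.5-fold minimum. Leaving out pairs gave 4 to 12, 4 to 7 and 1 to 7 calls. The paired differences stayed at 0 except for 0 to 1 calls when a pair was left out. The count of 25 over all windows was 7 with a 1.5-fold minimum, 12 with windows averaged, and 12 to 17 without 1 replicate number. Lists called per window (5, 6 and 4) fell to 0 with an estimated correlation, with or without the block, and to 0 with fry. Fry with the block called 3, 0 and 3 lists, not all the same: it added acute phase genes over T0 to T24 and ketogenesis over T24 to T30, where it did not call the core targets (adjusted p = 0.054). Leaving out 1 library gave 5 to 11, 2 to 9 and 3 to 6 lists. For T0 to T24 the list count was 9 without DMSO replicate 1, 8 without pemafibrate replicate 1, 9 without DMSO replicate 3 and 11 without pemafibrate replicate 3. The shared calls were 0 unpaired and, with the block, 3 between the 6 h windows and 4 between T0 to T24 and each of them, and 0 at adjusted p under 0.01. The cause of these moves was not tested unless stated.

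Core genes near 0 changed sign when 1 library was left out, with no call involved. Over T0 to T24 the ranges were −0.29 to 0.39 for Cd36, −0.097 to 0.15 for Pex11a, −0.052 to 0.21 for Ehhadh, −0.13 to 0.15 for Vnn1 and −0.057 to 0.0014 for Acadm. Over T14 to T20 they were −0.018 to 0.071 for Vnn1, −0.14 to 0.24 for Pex11a, −0.21 to 0.027 for Cd36 and −0.079 to 0.23 for Acsl1. Over T24 to T30 they were −0.0097 to 0.11 for Ehhadh, −0.046 to 0.093 for Vnn1, −0.11 to 0.081 for Pex11a and −0.12 to 0.14 for Acsl1. The other settings changed no sign of the 47 gene values tested.

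The count tests in edgeR and DESeq2 and the alternatives for DMSO libraries between windows were not run, since whole reads were not recovered. Without read depth, counting error of low genes is not known.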

Other observations

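The comparison of replicate numbers and its test of splits were chosen after the data had been seen. Replicate numbers differed in sterol genes in ways that the comparisons above do not describe. Of 13258 genes, 8981 (67.7%) differed between the 3 replicate numbers in limma, with group as a covariate and 6 libraries per number. All 24 measured cholesterol synthesis and uptake genes differed, with medians higher than in replicate 1 by 0.62 on the log2 scale in replicate 2 and by 0.89 in replicate 3 (camera adjusted p = 1.2e-19 and 4.9e-22). Idi1, of the isoprenoid pathway, averaged 1452 ± 235 (SD, n = 6), 2815 ± 364 and 3749 ± 339 in replicates 1, 2 and 3. The hepatocyte marker list was not called (medians −0.10 and −0.095, camera adjusted p = 0.113 and 0.060). Named after their values were seen, albumin (Alb) was 6657 ± 311, 3784 ± 272 and 3263 ± 132, and Apoe was 867 ± 87.7, 442 ± 65.2 and 194 ± 23.2.

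The cell cycle list was higher in replicate 3 than in replicate 1 by a median of 0.46 (adjusted p = 3.8e-12) and was not called in replicate 2 (median −0.054, adjusted p = 0.205). Ribosomal protein genes were higher in replicates 2 and 3 than in replicate 1 by 0.24 and 0.27 (adjusted p = 6.9e-10 and 2.8e-10). Of 100 drawn reassignments of the numbers within groups, 1 gave 8981 genes, the real one, a share under 0.05, and the highest other gave 6085. Reassignments keep part of the true numbers together, so their counts are not those of unrelated libraries. A difference between culture batches, such as passage, density or serum, is a candidate explanation that the labels do not let be tested.

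Fabp1, a liver fatty acid binding protein and PPARα target, lay below the minimum level but was higher with pemafibrate in 9 of 9 pairs. It was listed at 0 in 7 of 9 DMSO libraries, with a highest DMSO value of 2.00, and ran from 1.00 to 5.02 in the pemafibrate libraries. It was singled out after its values were seen and was not tested.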
